A study of Homo sapiens with 2 samples.

How the data were processed

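Gene expression was measured in 2 RNA samples of MDA-MB-231 cells, 1 of control cells and 1 of cells overexpressing CEBPB, on 1-colour Agilent human expression arrays. Per the labels' protocols, cells were grown in DMEM with serum and antibiotics, total RNA was extracted with TRIzol, its integrity was inspected, and it was purified on a column with DNase treatment. It was then amplified and labelled with Cy3 in a low-input one-colour kit. Per the file headers, both arrays lay on 1 slide and were scanned in 1 scan, so slide and scan do not differ between the groups. How the control cells and the CEBPB cells were made, and whether they are a pool or a clone, is not given in the sources used here.

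Per the file headers, spot intensity was extracted with Feature Extraction 10.7.3.1, which subtracted background, corrected spatial and multiplicative trends and flagged spots well above background. The submitters' processing notes name Agilent Feature Extraction 10.7. The probe coordinates in the files are on hg19 and are printed as given there. The deposited value table held log2 values for 41091 probes. Set against the scanner files, its columns correlated with log2 processed signal at r = 0.9999 and 1.00, and its sorted columns differed by at most 0.0067, as quantile normalization gives. Its medians were 5.55 for the control array and 5.55 for the CEBPB array. The scale (log2) and direction (higher values for brighter spots) were settled in this way, values were not centred on 0, and the tool and settings behind the table are not given in the sources used here.

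Processed signals were averaged over the spots of a probe after control spots and outlier spots were left out (90 and 99 of 43376 non-control spots on the control and CEBPB arrays); 0 spots were saturated. Log2 signal minus the array's own 75th percentile (487 and 493 in signal units) gave the normalized value. Probes were named through RefSeq accessions in the reference table of the GRCh38 assembly, used for names only. Of 40998 probes used, 27294 were named by accession, 2383 by a current symbol and 454 by an older symbol, and 10867 stayed unnamed. The named probes covered 18885 genes. A gene was represented by its brightest probe among those well above background on both arrays. Of 188 genes past 2-fold, 31 had more than 1 such probe, and for 1 gene another probe went the other way. 110 probes target the strand opposite to their gene, and for 12 genes such a probe was the brightest. No genome or gene annotation of the files' build was used here, so exon and untranslated region status comes from transcript positions in the files and general knowledge of CEBPB.

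With 1 array per group no test between groups was possible. The number of arrays limits the precision. Genes were described by a size rule, at least 2-fold or 4-fold, for genes well above background on both arrays. For a gene above background on 1 array only, the fold is a lower bound: its signal there against the higher of its own value on the other array and the lowest signal of any probe well above background there. It is a bound under the main background correction only, since fewer such genes reached 2-fold with normexp. It is also nominal, because a probe's own detection limit may lie above that lowest signal. C3, at a signal of 14.8 on the control array, was not above background there, while the lowest signal well above background was 14.0. Technical error was taken from the software's own spot error and from probes with repeated spots (203 and 214 probes), whose median SD was 0.08 and 0.069 on the log2 scale. Neither covers differences between cultures. For 28 gene lists fixed before the data were examined, the median difference was placed among 10000 random lists of equal size matched on mean signal in 20 bins. A list among the lowest or highest 2.5% was taken as standing apart, for these arrays only. As many lists were compared, some are outside these limits by chance.

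The genes named were set by a rule: the C/EBP family, the 12 largest increases and the 12 largest decreases, the 4 largest bounds on each side, and from each list up to 4 members with the largest difference and any member with a bound of 2-fold or more. The first 2 groups of 12 took genes with a gene symbol, unsaturated on both arrays, past 2-fold in the same direction under the main and the normexp setting, with other probes above background not going the other way. Y-linked genes and XIST were left out. In addition PTX3, MMP9, PLAU, VIM, GCLC, HMOX1, NQO1, OSGIN1, DSC2, CD3E and KDR, within the lists, were named after their values were seen. So were COL1A2, COL3A1, DCN, PTPRC, LYZ, CDH1, KRT5 and TP63, as list members not above background on the control array. Some single genes are not reported here.

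Median centring lowers every difference by one constant and leaves the order of genes and lists unchanged. Alternatives were normexp background correction (offset 50) on mean and local background signals, median centring, quantile normalization, removal of the intensity trend by loess (span 0.3), no filter and a stricter filter on dim probes, the mean over a gene's probes, the deposited value table, another detection flag and 10 bins for the matched lists. Probes with a RefSeq accession on the gene's own strand, and the CEBPB coding-sequence probe under each setting, were added after the data were seen. The procedure was tested on simulated data: 200 of 12883 genes were shifted by a known fold under the spot noise, and 1.5% were past 2-fold at a true 1.5-fold, 50.0% at 2-fold, 99.5% at 3-fold and 100% at 4-fold. Random lists fell outside the limits in 5.25% of 400 draws, a share that the limits largely fix in advance. These checks hold spot noise only, and leave out differences between cultures and shared regulation of genes within a list. Analyses used R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.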

Results

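The data comprised 2 one-colour expression arrays of MDA-MB-231 cells, a human triple-negative breast cancer line with a mesenchymal, highly migratory phenotype. 1 array held RNA of control cells and 1 held RNA of cells made to overexpress CEBPB, the gene of the transcription factor C/EBPβ, which drives acute-phase and inflammatory gene expression. The study addressed how CEBPB acts on downstream genes in breast cancer cell migration. Of 40998 probes, 24965 (60.9%) were well above background on the control array and 25576 (62.4%) on the CEBPB array. At gene level, 12883 genes were above background on both arrays, and their signals correlated at r = 0.992 across genes, which are not independent replicates. With 1 array per group, no difference has a replicate check, and every value describes these 2 arrays. Differences are CEBPB array minus control array in normalized log2 signal.

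CEBPB itself differed by probe. The probe at transcript position 793 (chromosome 20, 48807913 to 48807972, hg19), whose bases encode part of the C/EBPβ protein, gave a signal of 38.1 on the control array and 221 on the CEBPB array. This was a 5.74-fold higher signal, a difference of 2.52 with a software error of 0.23. The difference was 1.45 after normexp background correction. The brighter probe at transcript position 1869 (chromosome 20, 48808989 to 48809048) lies 1076 bases further downstream, which places it beyond the coding sequence, and its signal was 4570 and 4760, a difference of 0.04. That probe would not see an introduced copy that lacks the 3' untranslated sequence. Whether the introduced copy carries that sequence is not given in the sources used here, so it is open whether this probe checks the label. A probe for the opposite strand differed by 0.09. Among the other family members, CEBPD, an inflammation-induced relative, was 1.98-fold higher and CEBPE 1.81-fold higher. CEBPE was dim, with signals of 33.8 and 62.0, and its difference with normexp was 0.33, against 0.92 for CEBPD. CEBPA, CEBPG and DDIT3 differed by -0.24, -0.13 and -0.15. None of the 6 family genes reached 2-fold by its brightest probe.

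**Figure D1:**
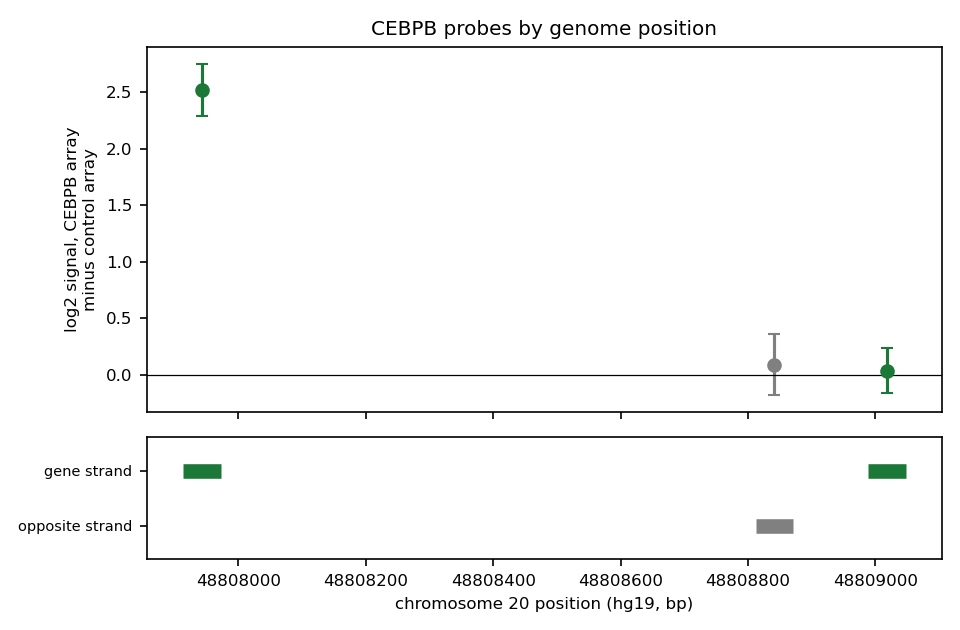
Difference in log2 signal between the CEBPB and control arrays for the 3 CEBPB probes, plotted by hg19 position on chromosome 20, with the scanner software's error of the difference as bars; the lower panel shows each probe's extent and target strand. The upstream probe lies at 2.52, and the other probes lie at 0.09 and 0.04.

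The cells labelled as overexpressing CEBPB had far higher levels of secreted proteases, protease inhibitors and inflammatory mediators. MMP3 and MMP1, which encode the matrix-degrading enzymes stromelysin and interstitial collagenase, were 376-fold and 256-fold higher. SLPI, an epithelial inhibitor of leukocyte elastase, was 246-fold higher, and its relative PI3 (elafin) was 19.4-fold higher. ALOX5AP, needed for leukotriene synthesis, was 96.4-fold higher and PTGS2, the inducible cyclooxygenase, 26.2-fold higher. The neutrophil chemokine CXCL1 was 48.3-fold higher and the cytokine IL6 17.0-fold higher.

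The other genes among the 12 largest increases were NNMT (39.6-fold), a nicotinamide methyltransferase, KYNU (30.4-fold), which cleaves kynurenine, SERPINB2 (19.0-fold), an inhibitor of plasminogen activators, and CSTA (18.3-fold), a cysteine protease inhibitor. Several genes were above background on the CEBPB array only, which gives a nominal lower bound under the main background correction. The true fold may be smaller, and no bounds with normexp are given for these genes. IL1B, a central inflammatory cytokine, was at least 264-fold higher. The neutrophil chemokine CXCL8 was at least 34.1-fold higher, the decoy receptor IL13RA2 at least 33.7-fold higher and CSF3, the granulocyte growth factor, at least 28.6-fold higher. Most of these genes were dim on the control array, so their folds depend on the background correction. With normexp the fold was 122 for MMP3, 228 for MMP1, 56.9 for SLPI, 32.9 for ALOX5AP, 22.5 for CXCL1, 11.6 for PTGS2 and 5.57 for IL6. It was 13.1 for NNMT, 9.81 for KYNU, 6.72 for PI3, 6.13 for CSTA and 5.11 for SERPINB2, and the naming rule took only genes past 2-fold under both settings.

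The lower genes differed by smaller amounts. FUT8-AS1, a long non-coding RNA, was 9.18-fold lower by its brightest probe, while its other probe differed by -0.21. RDH16, a retinol dehydrogenase, was 7.99-fold lower. UCA1, a long non-coding RNA first described in bladder cancer, was 5.10-fold lower. TIMP3, a matrix-bound inhibitor of metalloproteinases, was 4.67-fold lower and KISS1, known as a metastasis suppressor, 4.37-fold lower. CCL2, a monocyte chemokine, was 3.41-fold lower, in the direction opposite to CXCL1. The other genes among the 12 largest decreases were KRTAP2-3 (4.49-fold), SSTR2 (3.65-fold), STXBP6 (3.61-fold), PRICKLE1 (3.44-fold), SLAMF7 (3.43-fold) and F13A1 (3.33-fold). The other SSTR2 probe differed by -0.55. Above background on the control array only were FAM50B, at least 19.9-fold lower on the CEBPB array, ZBTB16, at least 8.11-fold lower, OTOP3, at least 6.46-fold lower, and COCH, at least 6.41-fold lower. These nominal bounds hold for the main background correction only. With normexp FUT8-AS1 was 2.75-fold, RDH16 2.58-fold, STXBP6 2.35-fold, SSTR2 2.04-fold and F13A1 2.02-fold lower.

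**Figure D2:**
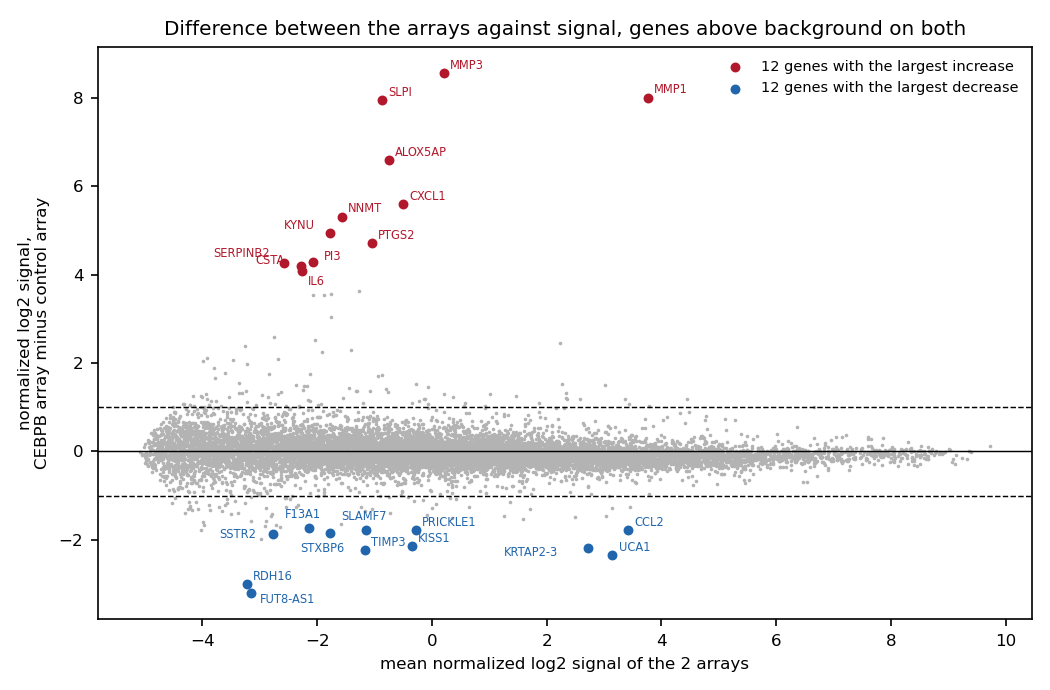
Difference in normalized log2 signal, CEBPB minus control array, against the mean of both arrays for the 12883 genes above background on both, with dashed lines at 2-fold. Red points are the 12 named genes with the largest increase, from IL6 at 4.09 to MMP3 at 8.55, and blue points the 12 with the largest decrease.

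Over all genes above background on both arrays, 109 were at least 2-fold higher and 79 at least 2-fold lower on the CEBPB array. At 4-fold the counts were 27 and 6, or 18 and 1 with normexp and 4 and 3 with a stricter filter on dim probes. The remaining 98.5% of genes lay within 2-fold, and 94.4% within 1.5-fold. With normexp, 52 genes were at least 2-fold higher and 29 lower, of which 51 and 29 were among those of the main setting, and with the stricter filter 30 and 24. A further 69 genes above background on the CEBPB array only, and 50 on the control array only, had a bound of 2-fold or more. These counts were 14 and 6 with normexp and 302 and 258 with another detection flag.

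The list with the highest median was that of acute-phase and innate genes, drawn up as genes bound by C/EBP factors, with no binding measured here. Of its 25 genes, 9 were above background on both arrays, with a median difference of 1.08, above every one of 10000 matched random lists. Of these, 5 were at least 2-fold higher, 0 were at least 2-fold lower and 4 were in between. The members included SERPINA1, the liver-type elastase inhibitor, 4.77-fold higher, and PTX3, a soluble pattern-recognition protein, 2.11-fold higher. A further 5 had a bound of 2-fold or more on the CEBPB array: C3 (6.34-fold), SAA1 (6.23-fold), S100A8 (5.57-fold), S100A9 (3.05-fold) and HP (2.80-fold). These nominal bounds hold for the main background correction, and S100A9 and HP were dim on the CEBPB array, with signals of 43.1 and 39.6. With the 7 members above background on the CEBPB array only at their bounds the median was 1.55, a value with no random lists beside it. It leaves out the 9 members above background on neither array, and with no filter the median over all 25 was 1.08. With normexp SERPINA1 was 3.03-fold and PTX3 1.96-fold higher.

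Cytokines and chemokines had a median difference of 0.69 over 12 genes, also above all 10000 random lists, and of 0.33 with normexp. 4 were at least 2-fold higher, CXCL1, IL6, CXCL2 (12.3-fold) and CXCL3 (4.92-fold), 1 was at least 2-fold lower, CCL2, and 7 were in between. IL1B, CXCL8, CSF3, IL1A and CCL20 were at least 2-fold higher as nominal bounds under the main background correction. IL1A and CCL20 were dim on the CEBPB array, with signals of 39.2 and 37.7. CXCL2 was 5.53-fold and CXCL3 3.27-fold higher with normexp. NF-kappaB feedback and target genes had a median of 0.36 over 14 genes, above all 10000 random lists, and of 0.23 with normexp. 3 of them were at least 2-fold higher: ICAM1 (3.16-fold), a leukocyte adhesion molecule, RELB (2.38-fold), an NF-kappaB subunit, and BCL3 (2.26-fold), a nuclear partner of NF-kappaB. The other 11 were within 2-fold, and ICAM1 was 1.53-fold higher with normexp. Interferon-stimulated genes differed little, with a median of -0.08 over 19 genes at the 31.96 percentile, and 0 of 19 reached 2-fold. XAF1 was at least 5.26-fold lower as a nominal bound.

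Genes of matrix breakdown and migration moved unevenly. Of 23 matrix protease and plasminogen genes, 3 were at least 2-fold higher (MMP1, MMP3 and SERPINB2), 2 at least 2-fold lower (TIMP3 among them) and 18 in between. Their median was 0.10, at the 99.49 percentile, and 0.04 at the 93.78 percentile with normexp. MMP9 differed by -0.01 and PLAU, the urokinase activator, by -0.75. Integrins had a median of 0.13 over 14 genes at the 97.48 percentile, just inside the limits, with 1 gene, ITGA1, 2.68-fold higher, which was 1.95-fold with normexp. Actin and motility genes had a median of -0.14 at the 3.34 percentile, with 28 of 36 below 0 and 0 at 2-fold, and of -0.08 with quantile or loess normalization. The median over all genes was itself below 0, at -0.06. Of 23 extracellular matrix genes, 1 was at least 2-fold higher, LOX (2.12-fold, or 1.88-fold with normexp), a collagen crosslinker. The median was -0.01 with a mean of 0.00 and turned above 0 with normexp, quantile or loess normalization and in the authors' table, and with the stricter filter. Of 10 mesenchymal transition genes, 1 was at least 2-fold higher, TGFBI (2.27-fold), and VIM, the intermediate filament vimentin, differed by 0.04. The mesenchymal median of 0.10 lay at the 96.93 percentile, and was 0.01 with normexp and -0.03 with the stricter filter. Epithelial junction and keratin genes had a median of 0.00 over 24 genes at the 86.87 percentile, which was below 0 with normexp and with median centring, and 0 of 24 reached 2-fold. TGF-beta target genes had a median of 0.10 at the 98.44 percentile and 0 of 18 at 2-fold. Their percentile was 90.85 with quantile and 91.18 with loess normalization and 91.25 in the authors' table, inside the limits.

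Proliferation and sterol genes were slightly lower as groups. Of 36 cell cycle genes, 34 were below 0 and 0 reached 2-fold, with a median of -0.21 at the 0.02 percentile. CDC25A, a cell cycle phosphatase, differed by -0.52 and CCND1, cyclin D1, by -0.46. With normexp this median was -0.12 at the 15.15 percentile. Cholesterol synthesis genes had a median of -0.25 over 19 genes at the 0.06 percentile, with 18 below 0 and 0 at 2-fold. MSMO1 differed by -0.61 and MVD by -0.46. Both medians were below 0 under every scaling tried but smaller under some. Cell cycle was at -0.13 with quantile and -0.11 with loess normalization, and cholesterol synthesis at -0.15 and -0.14, and -0.15 in the authors' table. The counts below 0 do not set these lists apart by themselves, since the median over all genes was -0.06. Among reference groups, 19 of 20 housekeeping, 26 of 38 ribosomal protein and 20 of 27 respiratory chain genes were also below 0. The percentiles, matched on signal, allow for this offset.

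Among stress and metabolic lists, oxidative stress and metallothionein genes had a median of 0.19 over 19 genes, above all 10000 random lists. 2 were at least 2-fold higher, AKR1C1 (11.7-fold, or 4.89-fold with normexp) and AKR1C3 (2.47-fold), aldo-keto reductases. Their sequences are close enough that probes may pick up the other copies, AKR1C2 included, so the assignment is uncertain. MT1F differed by 0.59 and MT1A by 0.37. The metallothionein probes share sequence in the same way, so they are not independent members, while the random lists treat them as separate genes. The other oxidative stress genes went both ways, with GCLC at 0.16, HMOX1 at 0.09, NQO1 at -0.16 and OSGIN1 at -0.18. Hypoxia and glycolysis genes had a median of 0.05 over 28 genes, above all 10000 random lists and below 0 with median centring, with 1 at least 2-fold higher, VEGFA (2.33-fold), an angiogenic growth factor. Stress-response genes of the integrated stress and unfolded protein pathways had a median of 0.04 at the 99.59 percentile, below 0 with median centring and with the stricter filter, and 0 of 25 reached 2-fold. In this list SLC7A11, a cystine transporter, was 1.57-fold higher. The fatty acid list had a median of -0.03 and a mean of 0.02 at the 77.84 percentile. This median was above 0 with normexp, quantile and loess normalization, as a mean over probes and in the authors' table. Its 1 gene at 2-fold or more was G0S2, a lipolysis inhibitor, with normalized signals of 6.15 and 7.15, and 1.99-fold with normexp.

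**Figure D3:**
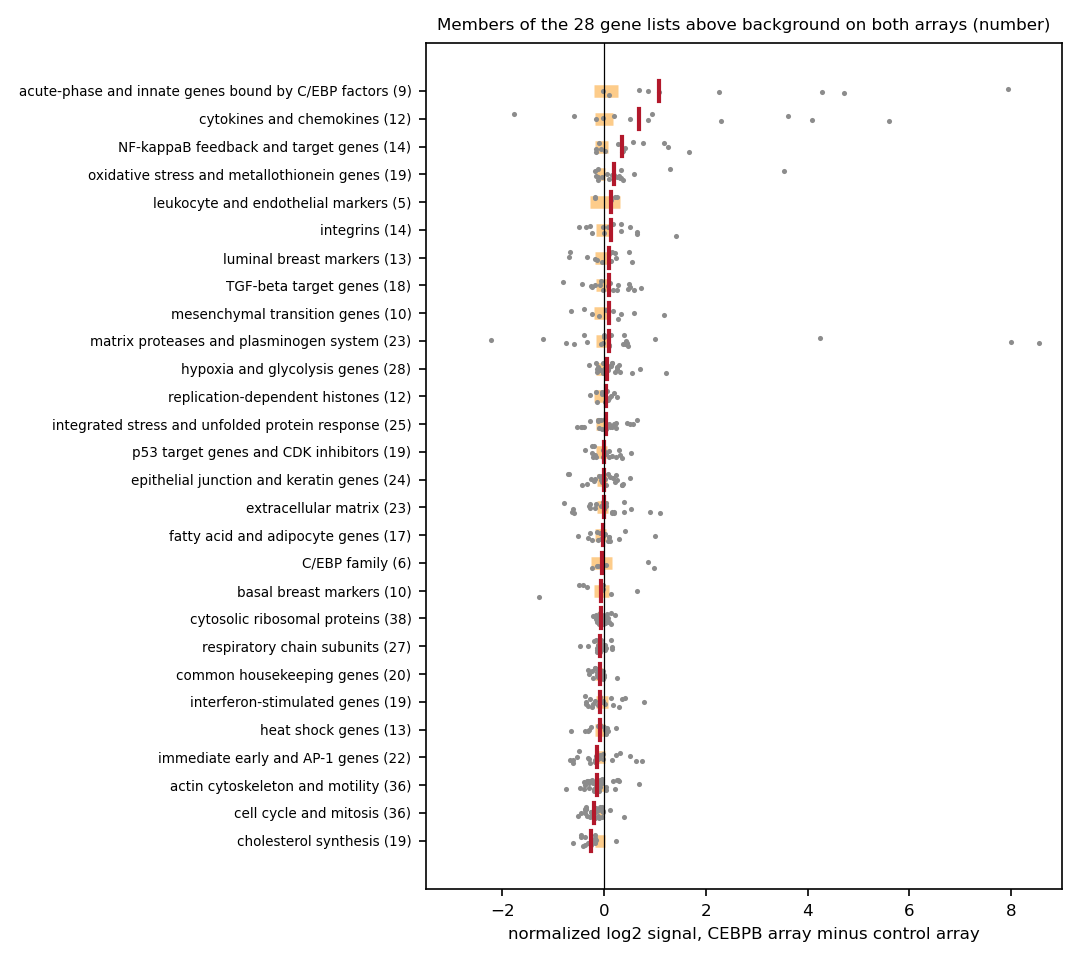
Difference in normalized log2 signal, CEBPB minus control array, of the members of the 28 gene lists above background on both arrays (grey points, number in brackets), with each list's median (red line) and the central range of 10000 matched random lists (orange bar, leaving out 2.5% at each end). The acute-phase median of 1.08 lies furthest right and the cholesterol synthesis median of -0.25 furthest left.

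The remaining lists served as markers of cell identity and as reference groups. Luminal markers had a median of 0.10 and a mean of -0.02 over 13 genes at the 97.30 percentile. This median was -0.05 with no filter and -0.04 with the stricter filter on dim probes. Basal markers had a median of -0.06 over 10 genes at the 56.15 percentile, with ID4 2.45-fold lower, or 1.92-fold with normexp. Leukocyte and endothelial markers had a median of 0.13 over 5 genes at the 82.34 percentile, 0 of them at 2-fold, and 11 of the 18 on the arrays were above background on neither. Immediate early and AP-1 genes had a median of -0.14 at the 8.85 percentile (-0.05 in the authors' table), p53 targets 0.00 at the 82.42 percentile and heat shock genes -0.09 at the 53.55 percentile. The p53 median lay just below 0 and was above 0 with normexp, quantile and loess normalization and in the authors' table. Ribosomal protein, housekeeping and respiratory chain genes had medians of -0.07, -0.08 and -0.08 at the 87.58, 76.51 and 81.04 percentiles. With loess each of these 3 medians turned above 0, as did the ribosomal and respiratory medians with quantile normalization and in the authors' table. Histone genes had a median of 0.04 over 12 genes at the 97.99 percentile, below 0 with median centring. The C/EBP family had a median of -0.04 and a mean of 0.23 at the 61.08 percentile, and its median was above 0 with normexp, quantile and loess normalization and in the authors' table.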

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

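Of the tests below, those on RNA integrity were chosen before their result was seen, and all others after it.

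Probes without a gene name stood outside the gene comparison, and 39 of the 4381 above background on both arrays were at least 2-fold higher on the CEBPB array, above their control level, and 24 were at least 2-fold lower. The largest of the higher probes, THC2674530 (chromosome 16, 69347746 to 69347805, hg19), differed by 2.04.

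The CEBPB coding-sequence probe was higher while the downstream probe was not. An exchange of the array labels would place it lower on the CEBPB array, and its difference of 2.52, with an error of 0.23, goes against that. That value comes from 1 dim probe with 1 spot per array, and the brighter probe, at 0.04, speaks neither way. A difference in RNA integrity or amplification length between the arrays would raise upstream probes of other genes alike. Over 2269 genes with probes at least 1 kb apart, the median upstream minus downstream difference was 0.016, with an error of 0.006, while the 2 CEBPB probes differed by 2.52 and 0.04. A candidate explanation, an introduced coding sequence without the distal 3' untranslated sequence, remains open, because 0 other own-strand probes lie in the coding sequence.

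The difference between arrays fell with signal, from a median of 0.037 in the dimmest of 5 equal groups of genes to -0.112 in the brightest. Non-linear scanning or background subtraction would give the spike-in RNAs the genes' slope of -0.02 per log2 of signal. The 8 spike-ins above background had a slope of 0.002 (standard error 0.005), above the genes' slope by 0.021 (standard error 0.005). RNA integrity or amplification length was tested as a change per kb of probe separation at equal signal, and the coefficient over 4190 genes was -0.0044 (standard error 0.0024), within 0.05 of 0. A difference in RNA composition between the cell cultures stays open and was not tested.

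The acute-phase, cytokine and NF-kappaB lists stood higher on the CEBPB array, and of 23 protease genes 3 (MMP1, MMP3 and SERPINB2) were at least 2-fold higher and 2 at least 2-fold lower. The lowest percentile of the acute-phase, cytokine and NF-kappaB medians was 100 over the settings that gave a value. The stricter filter on dim probes gave a value for the NF-kappaB list only. These lists thus stood apart under each background correction and scaling tried, although median centring cannot change a rank. Quantile and loess scaling shift genes of like signal nearly alike, so they challenge a rank matched on signal only weakly. Normexp was the stronger challenge. The size of the shift did depend on them: normexp lowered the cytokine median from 0.69 to 0.33 and the NF-kappaB median from 0.36 to 0.23. The protease list fell to the 93.78 percentile with normexp, so its shift as a list may come from the background correction, although MMP1 and MMP3 stayed at least 228-fold and 122-fold higher under every setting that kept them. Admixed fibroblasts, leukocytes or other epithelial cells would bring their abundant transcripts, yet of 32 matrix, leukocyte, junction and basal list members not above background on the control array, among them COL1A2, COL3A1, DCN, PTPRC, LYZ, CDH1, KRT5 and TP63, 3 came above background on the CEBPB array (DSC2, CD3E and KDR) and 0 were 2-fold or more above it. This count covers those list members only. Leukocyte genes outside the lists were not counted, and some passed 2-fold in either direction, such as HCLS1 (3.39-fold higher) and SLAMF7 (3.43-fold lower). These examples are no tally by direction, so the count of list members does not settle whether leukocytes were admixed. A difference between the cultures other than CEBPB, such as clone, density or handling, cannot be told apart from CEBPB with 1 array per group, and the biological explanation by CEBPB itself is likewise untested.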

How the results depend on the processing

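Of these settings, the RefSeq own-strand probes and the CEBPB coding-sequence probe were chosen after seeing the data. No list passed from beyond 1 percentile limit to beyond the other. No paired analysis was possible because each group had 1 array; for the same reason no array could be left out, and the slide as a block was not run, since both arrays lay on 1 slide. Against 109 genes at least 2-fold higher and 79 lower, the counts were 52 and 29 with normexp, 770 and 616 with no filter on dim probes, and 30 and 24 with the stricter filter, which keeps only bright probes by construction. Against 27 and 6 at 4-fold, no filter gave 137 and 100, the stricter filter 4 and 3, and normexp 1 lower. Genes above background on 1 array only with a bound of 2-fold or more numbered 69 (CEBPB) and 50 (control), 14 and 6 with normexp, whose offset compresses dim signals, and 302 and 258 with the other detection flag. Other settings kept these counts within 1.5 times. The CEBPB difference of 0.04 by the brightest probe was -0.03 with median centring, 0.15 with quantile normalization, 0.15 with loess, 0.15 in the authors' table and 0.88 as a mean over probes, which brings in the coding-sequence probe; that probe's 2.52 was 1.45 with normexp. Of 276 list medians under alternatives, 257 stayed on the same side of the percentile limits. The stricter filter left too few members for the acute-phase, cytokine, C/EBP family and leukocyte lists. List medians that came to stand apart were the C/EBP family (0.37, mean over probes), integrins (0.16 normexp, 0.42 stricter filter, 0.18 RefSeq probes, 0.13 with 10 bins), actin genes (-0.08 loess, -0.20 stricter filter), extracellular matrix (0.06, stricter filter), and, with the mean over probes, mesenchymal genes (0.12), p53 targets (0.07) and ribosomal proteins (-0.04). Those that no longer did were proteases (0.04, normexp), TGF-beta targets (0.07 quantile, 0.08 loess, 0.02 stricter filter, 0.07 authors' table), cell cycle (-0.12, normexp), stress response (-0.04, stricter filter) and histones (0.02, mean over probes); apart from filters, the cause was not tested. Signal over background limits the dim genes most: 42 of the 109 higher and 42 of the 79 lower genes lay in the dimmest of 5 equal groups of genes.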

Other observations

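Genes outside the lists and the naming rule, chosen after their values were seen, include TNFRSF11B, the decoy receptor osteoprotegerin that restrains osteoclasts, 11.7-fold higher on the CEBPB array. S100P, a calcium-binding protein, was 8.27-fold higher, CDA, cytidine deaminase, 5.74-fold higher and EPAS1, the hypoxia-inducible factor HIF-2α, higher by 2.46 on the log2 scale. ZC3H12A, an RNase that degrades inflammatory transcripts such as that of IL6, was 2.87-fold higher, and IL7R, IL1RAP and IL4R, cytokine receptor chains, were 2.73-fold, 2.46-fold and 2.03-fold higher. With normexp TNFRSF11B was 5.61-fold, S100P 4.28-fold, CDA 3.06-fold and IL1RAP 1.71-fold higher. NAMPT, the rate-limiting enzyme of NAD salvage, was 2.89-fold higher.

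Among lower genes chosen the same way, ANKRD1 was 2.87-fold lower, RASD1 2.77-fold lower and EDN1, the vasoconstrictor endothelin-1, 2.75-fold lower. SOX9, a transcription factor of progenitor cells, was 2.54-fold lower, FST, the activin antagonist follistatin, 2.45-fold lower and SOD3, extracellular superoxide dismutase, 2.37-fold lower. Of the unnamed probes, the one at chromosome 6, 107956362 to 107956421 (hg19), differed by -3.59, and AA837799, at chromosome 22, 33198429 to 33198488, upstream of the TIMP3 probe at 33258540, was 4.04-fold lower.

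All 3 hypotheses below were formed after the result was seen. The first is that the strongly higher genes lie near each other by chance placement. Among the 27 genes at least 4-fold higher, 5 pairs lay within 500 kb: MMP1 with MMP3, PI3 with SLPI, and the 3 pairs among CXCL1, CXCL2 and CXCL3. Of 10000 random sets of as many measured genes, 0.01% held as many pairs. The closeness was seen in these same genes before the count was made, so this share is no test of chance placement. These genes are also paralogs in clusters, and sequence shared between paralogs could contribute.

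The second hypothesis was that kynurenine and NAD metabolism genes rise together with KYNU and NNMT. Without KYNU and NNMT, which prompted it, the other 11 measured members had a median difference of -0.05, at the 58.65 percentile of matched random lists, with NAMPT at 1.53, NMRK1 at 0.42 and KMO at -0.33. As a set these members were not higher than random lists on these 2 arrays. Single members went both ways, and a percentile between the limits leaves this hypothesis undecided. The third was that metastasis suppressor genes fall together with KISS1 and TIMP3. The other 13 members had a median of -0.08 at the 48.59 percentile, with ARHGDIB at -0.55, GSN at -0.43 and NDRG1 at 0.25. As a set they were not lower than random lists on these 2 arrays, and a percentile between the limits likewise leaves the hypothesis undecided.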
